A study of Mus musculus with 6 samples.

How the data were processed

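RNA was measured in 6 libraries of live CD45+ CD4+ Foxp3-GFP+ cells sorted from mouse tumours, made with a stranded total RNA kit (SMARTer Stranded Total RNA-Seq Kit v2), per the labels' protocols. The authors deposited 1 table per library of raw read counts per gene, not normalized. Reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 2.1.0 to mm10 and counted with HTSeq, and DESeq2 is also named, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart.

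Each table listed 54446 Ensembl genes, of which 54409 matched the GENCODE M21 annotation by identifier, from which symbols and coordinates (mm10) were taken. Rows that name no gene stayed out of library sizes and tests. Reads in no gene made up 24.6% to 35.8% of all records, ambiguous reads 1.43% to 2.21% and reads aligned to several places 9.22% to 12.9%. The spike-in rows held at most 1 count per library. Groups, replicate numbers and cages came from the sample titles. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 16.8), so all 6 were counted as separate.

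Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), scaled by TMM and tested with the edgeR quasi-likelihood test in R 4.3.3, all 6 libraries in 1 fit with the group as the only term. P-values were adjusted by Benjamini and Hochberg over the 13172 genes, with a threshold of 0.05. CPM values use TMM-scaled library sizes, except the sums of cell-type markers, which use total gene counts without the TMM factors. Fold changes are log2 of the libraries labelled Ythdf2 cKO over control. Before the data were examined, 46 gene lists were fixed, and the 43 with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. None of the 43 passed with an estimated correlation or with fry, a rotation test of whether a list moves on balance one way. Library measures were compared by exact two-sided permutation.

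Named genes followed a rule set at the same time: Ythdf2, then the genes with the smallest p past the threshold and those with the largest changes. Where fewer than 5 passed in a direction, the 5 with the smallest p were named instead, as not past it. Clone-like names and pseudogenes were passed over, and up to 4 members with the smallest p came from each list described. A gene that the rule names is not reported here. Foxp3 and Cd4 were added after their values were seen.

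Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, no filter and a stricter one (mean CPM of at least 5), mitochondrial, ribosomal RNA and haemoglobin genes left out, the replicate number as a block, cage as a term, each library left out, other thresholds and other list tests. Added after the data were seen were the melanoma markers as a covariate, sample quality weights, a GC content and exon length correction, cage with an estimated correlation, and leaving out both ends of the first principal component. On simulated counts with 200 changed genes the gene test made 0, 4 and 7 false calls at 2-fold, 4-fold and 8-fold. A simulated list of 50 genes shifted by -0.7 was called and 0 of 43 unshifted lists were. The simulated genes were drawn independently, so this does not check the list test on genes that move together. The estimated correlation of the histone list, for instance, was 0.38 against the preset 0.01. The smallest library held 5602053 gene counts and the largest 13602069, and read counts are not counts of independent molecules.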

Results

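Total RNA was sequenced from regulatory T cells (Treg cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses) sorted out of subcutaneous B16F10 tumours. B16F10 is a mouse melanoma cell line. Of the 6 libraries, 3 came from control mice, which carry the Foxp3-driven Cre recombinase and 1 floxed Ythdf2 allele, and 3 libraries are labelled Ythdf2 cKO, with both alleles floxed. The labels also place the mice in 2 cages. Control replicates 1 and 2 and Ythdf2 cKO replicate 1 came from cage 1, and control replicate 3 and Ythdf2 cKO replicates 2 and 3 came from cage 2. The libraries held 10515662, 13602069 and 8923124 gene counts in control replicates 1, 2 and 3, and 5602053, 9960861 and 9263893 in the libraries labelled Ythdf2 cKO. Nothing in the labels says that each library is a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

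The design asks how gene expression in tumour Treg cells changes when Ythdf2 is deleted. Ythdf2 encodes a reader protein that binds mRNAs carrying N6-methyladenosine (m6A) and promotes their decay. Its own transcript did not differ between the groups past the threshold. Ythdf2 (ENSMUSG00000040025, chromosome 4, 132184912 to 132212303, mm10) stood at 106 ± 15.9 CPM (read counts scaled to TMM-adjusted library size; SD, n = 3) in the controls and 99.5 ± 8.14 CPM (SD, n = 3) in the libraries labelled Ythdf2 cKO. The values were 124, 102 and 93.1 CPM in control replicates 1, 2 and 3 against 90.1, 104 and 104 CPM, so the library labelled Ythdf2 cKO lay below both controls in cage 1 and both lay above the control in cage 2. The log2 fold change was -0.10 with a standard error of 0.16 and a 95% interval from -0.47 to 0.28 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). The sign turned without control replicate 1 (0.023) and with total counts as the only scaling (0.021). The counts cover all exons of the gene, the labels do not say which exons the floxed allele removes, and a deletion that leaves most of the transcript in place would not show in them. Directions are therefore given for the libraries as labelled.

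Neither of the sort genes Foxp3 and Cd4 passed the threshold (edgeR adjusted p = 1). Foxp3 was at 423 ± 88.4 CPM in the controls and 442 ± 144 CPM in the libraries labelled Ythdf2 cKO (SD, n = 3 each), and Cd4 at 563 ± 153 and 566 ± 132 CPM. Tumour transcripts differed far more, and by cage. The mean of 15 melanoma markers was 3.55, 3.92 and 6.87 log2 CPM in control replicates 1, 2 and 3 and 1.14, 6.09 and 6.49 log2 CPM in the libraries labelled Ythdf2 cKO, so the 3 libraries of cage 2 were the 3 highest. Dct, an enzyme of melanin synthesis chosen after its values were seen, ran from 15.2 CPM in Ythdf2 cKO replicate 1 to 2013 CPM in control replicate 3. Mitochondrial ribosomal RNA took 42.6% of the gene counts in control replicate 3 and from 9.97% to 19.2% in the other libraries. Over all 6 libraries neither measure passed a test between the groups (exact two-sided permutation p = 0.9 for the melanoma markers and 0.8 for mitochondrial ribosomal RNA, adjusted p = 1 over 25 library measures; 3 against 3 cannot give a p below 0.1). Within each cage, though, each library labelled Ythdf2 cKO lay below each control in both measures. The median log2 difference of the melanoma markers was -2.95 within cage 1 and -0.78 within cage 2, and with cage as a term it was -1.44 (camera adjusted p = 3.80e-05; no list passed with cage and an estimated correlation). The first principal component held 59.4% of the variance and ran from -122.2 in Ythdf2 cKO replicate 1 to 75.0 in control replicate 3. Genes detected numbered 19931 ± 635 in the controls and 17252 ± 2163 in the libraries labelled Ythdf2 cKO (exact permutation p = 0.1, adjusted p = 0.83), and with reads drawn to a common depth 18007 ± 708 and 16358 ± 1737 (exact permutation p = 0.2, adjusted p = 0.83).

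**Figure D1:**
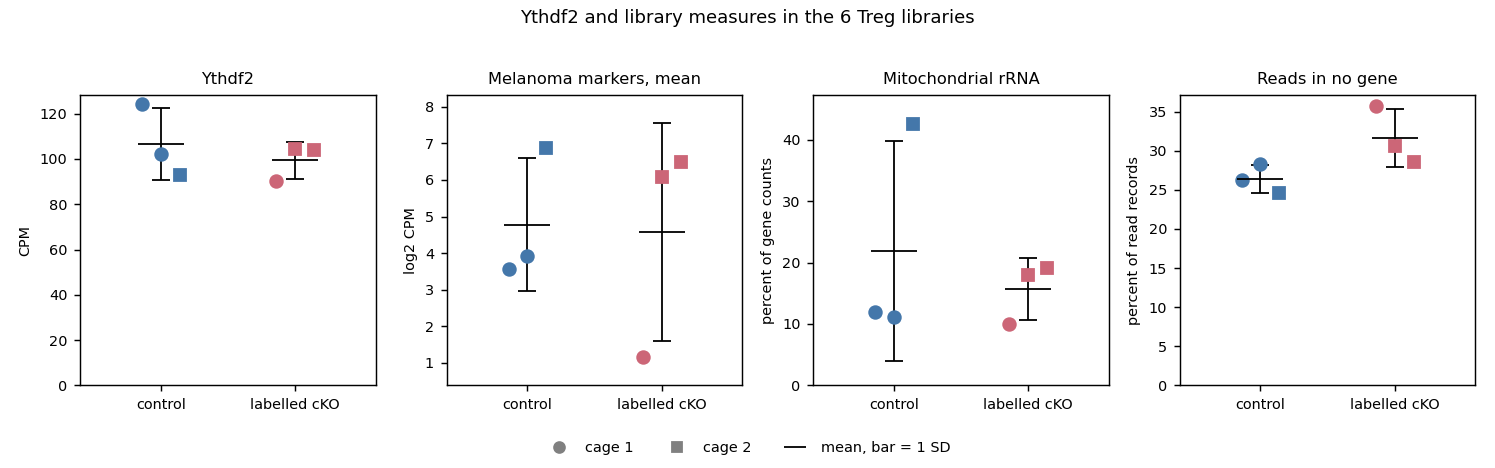
Ythdf2 in CPM, the mean log2 CPM of the melanoma markers, the percent of gene counts from mitochondrial ribosomal RNA and the percent of read records in no gene, for each of the 6 libraries. Circles are cage 1, squares cage 2, and black marks the mean with a bar of 1 SD over 3 libraries; Ythdf2 overlaps between the groups and the melanoma markers are highest in the 3 squares.

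No gene passed the threshold between the groups. Of 13172 genes tested, 0 were higher and 0 lower at an adjusted p under 0.05 with edgeR. An unadjusted p under 0.05 was found for 213, where chance gives 659 on average. Other splits of the 6 libraries into 3 and 3 gave from 114 to 2623. DESeq2 and limma-voom also called 0 genes, with 240 and 239 at an unadjusted p under 0.05. The groups did not overlap for 1004 genes, or 7.62%, where chance gives 10%. Counts were simulated for this comparison with the spread seen under the group as the only term. Of genes changed 2-fold 4.5% were recovered, of those changed 4-fold 56.5% and of those changed 8-fold 79%. Most changes of 2-fold would therefore not be detected with these libraries in that fit. A fit with cage as a term was not simulated.

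The genes with the smallest p, none past the threshold, included a nuclear RNA, linker and core histones and a pair of cytokine-related genes (edgeR adjusted p = 1 for each). Neat1 (chromosome 19, 5824708 to 5845478), the long noncoding RNA that builds paraspeckles, was at 105 ± 11.1 CPM in the controls and 163 ± 26.7 CPM in the libraries labelled Ythdf2 cKO (SD, n = 3; log2 fold change 0.64, standard error 0.17). Ubp1 was at 59.9 ± 1.38 and 82.4 ± 3.24 CPM, Homer1 at 41.1 ± 3.68 and 63.8 ± 9.64 CPM, and Emc4 at 3.12 ± 0.105 and 8.57 ± 1.83 CPM. Phka2, a subunit of phosphorylase kinase, had a log2 fold change of 0.98 with a standard error of 0.28. In the other direction, Il17rb, a receptor subunit for interleukin-25, was read 166 times in the controls and 3 times in the libraries labelled Ythdf2 cKO, a depth-adjusted ratio of 44.5 with a 95% counting interval from 15.0 to 218. Il5, the eosinophil growth factor, was read 198 and 11 times, a ratio of 14.5 with an interval from 7.92 to 29.5, and Gatm 73 and 5 times, a ratio of 11.7 with an interval from 4.81 to 37.3. These intervals cover counting error only and not the spread between libraries: Il17rb ranged from 1.89 to 8.66 CPM within the controls. Its log2 fold change was -5.28, and -4.55 without control replicate 1, and its 3 reads in the libraries labelled Ythdf2 cKO all came from replicate 3, without which the group held 0 and the fitted value depends on the prior count. That of Il5 was -3.82, and -5.00 without Ythdf2 cKO replicate 3 and -3.34 without Ythdf2 cKO replicate 1.

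**Figure D2:**
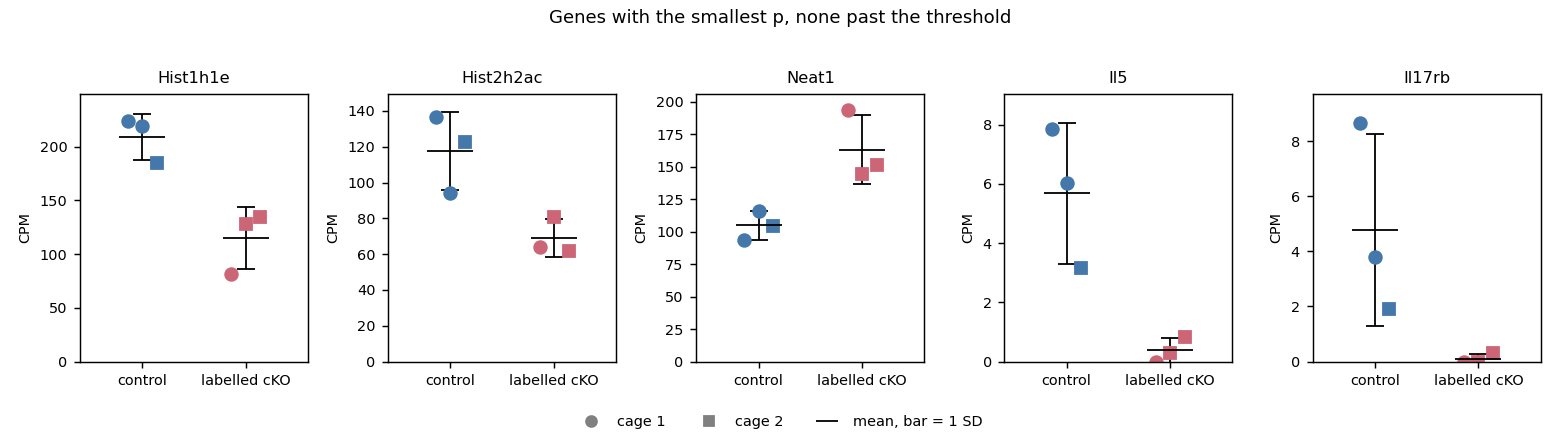
CPM of Hist1h1e, Hist2h2ac, Neat1, Il5 and Il17rb in each library, on linear axes from 0. Circles are cage 1, squares cage 2, and black marks the mean with a bar of 1 SD over 3 libraries; the groups do not overlap for these 5 genes, which were picked by their p.

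Replication-dependent histone genes, whose mRNAs lack poly(A) tails and whose proteins package newly made DNA, were lower as a group in the libraries labelled Ythdf2 cKO. Of 49 measured members, 47 had a log2 fold change below 0, with a median of -0.68 (camera with a preset correlation of 0.01, adjusted p = 6.10e-17 over 43 lists). The call was lost with the correlation between genes estimated from the data (adjusted p = 0.78 with an estimated correlation). Of single members, 0 passed when adjusted over all genes and 0 when adjusted over the list alone, and 12 had an unadjusted p under 0.05. Hist1h1e (chromosome 13, 23620629 to 23622558) was at 209 ± 21.6 CPM in the controls and 115 ± 28.9 CPM in the libraries labelled Ythdf2 cKO, Hist2h2ac at 118 ± 21.8 and 68.9 ± 10.5 CPM, Hist2h2bb at 40.4 ± 13.6 and 18.0 ± 4.81 CPM, and Hist1h2bb at 55.6 ± 2.75 and 34.7 ± 6.42 CPM (SD, n = 3). The median difference within cage 1 was -1.26 and within cage 2 -0.22. The mean deviation of the list overlapped between the groups (exact permutation p = 0.2). It was 0.14 in Ythdf2 cKO replicate 2 and -0.011 in control replicate 3. Some histone genes are near-identical copies, so their counts depend on how shared reads were handled. Reads aligned to several places were held in a row that names no gene and stayed out of the tests.

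Cytosolic ribosomal protein genes were lower as a group under the preset correlation, with a median log2 fold change of -0.22 and 71 of 72 members below 0 (camera adjusted p = 1.39e-08; adjusted p = 0.96 with an estimated correlation). Rpl38 was at 176 ± 13.3 CPM in the controls and 138 ± 1.67 CPM in the libraries labelled Ythdf2 cKO, and Rpl21 at 116 ± 16.2 and 87.4 ± 11.7 CPM (SD, n = 3). The median was -0.40 within cage 1 and 0.020 within cage 2. It was -0.11 without control replicate 1, -0.10 with total counts as the only scaling and -0.11 with a correction for GC content and exon length. Of single members, 2 had an unadjusted p under 0.05, and 0 passed when adjusted over all genes or adjusted over the list alone.

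Genes of the cell cycle were lower too under the preset correlation. G2/M and mitosis genes had a median log2 fold change of -0.28, with 34 of 42 members below 0 (camera adjusted p = 0.0014; adjusted p = 0.96 with an estimated correlation). Birc5, the survivin gene, was at 33.2 ± 6.80 CPM in the controls and 20.1 ± 7.28 CPM in the libraries labelled Ythdf2 cKO, and Mki67, a marker of dividing cells, at 1010 ± 226 and 768 ± 157 CPM. With each library left out, the log2 fold change ran from -0.98 to -0.47 for Birc5 and from -0.52 to -0.23 for Mki67. The call ended without Ythdf2 cKO replicate 1 (0.029) and with sample quality weights (-0.18). The median was -0.18 without control replicate 1, -0.44 without Ythdf2 cKO replicate 3, -0.15 with total counts and -0.50 with cage as a term, and it was -1.11 within cage 1 and 0.017 within cage 2. The list and the melanoma markers were both lowest in Ythdf2 cKO replicate 1, at -0.94 and -3.53 from the mean of the 6 libraries. S phase and DNA replication genes had a median of -0.18, with 32 of 40 members below 0 (adjusted p = 0.030; adjusted p = 0.96 with an estimated correlation). Dut was at 55.9 ± 8.59 and 44.6 ± 6.26 CPM and Uhrf1 at 96.7 ± 19.6 and 78.0 ± 6.25 CPM. Their log2 fold changes ran from -0.44 to -0.20 and from -0.45 to -0.16 with each library left out. The S phase call ended without control replicate 1 (-0.040), Ythdf2 cKO replicate 1 (-0.14) or Ythdf2 cKO replicate 3 (-0.15), with total counts as the only scaling (-0.053), with cage as a term (-0.15), without the low-count filter (-0.18) and with the GC content and length correction (-0.14). It was lost in 12 of 23 alternatives, and the median was -0.37 within cage 1 and -0.052 within cage 2. In both lists 0 members had an unadjusted p under 0.05, and 0 passed when adjusted over all genes or adjusted over the list alone.

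Interferon response genes were higher as a group under the preset correlation. Of 58 members 47 were above 0, with a median log2 fold change of 0.20 (camera adjusted p = 0.011; adjusted p = 0.96 with an estimated correlation). Rsad2, an antiviral enzyme, was at 5.44 ± 3.33 CPM in the controls and 11.2 ± 4.75 CPM in the libraries labelled Ythdf2 cKO, and Iigp1 at 94.3 ± 32.2 and 146 ± 51.6 CPM. With each library left out, the log2 fold change ran from 0.60 to 1.47 for Rsad2 and from 0.30 to 0.91 for Iigp1. Mx1 was at 31.3 CPM in Ythdf2 cKO replicate 1 and between 2.65 and 5.21 CPM in the other libraries. Without that library the median of the list was -0.11, and the call also ended without control replicate 1 (0.15) or control replicate 3 (0.22), with limma-voom (0.13) and with sample quality weights (-0.041). The median was 0.35 without control replicate 2, 0.33 without Ythdf2 cKO replicate 2 and 0.40 without Ythdf2 cKO replicate 3. It was 0.37 with total counts, 0.34 with cage as a term, 0.35 with the GC content and length correction and 0.12 with the melanoma covariate, and it was 0.69 within cage 1 and -0.030 within cage 2. The member with an unadjusted p under 0.05 was Ifi208, which lay in the other direction with a log2 fold change of -0.93 and a standard error of 0.40 (-0.47 without control replicate 2), and 0 passed when adjusted over all genes or adjusted over the list alone.

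T helper 17 genes were also higher as a group, with 7 of 9 members above 0 and a median log2 fold change of 0.25 (camera adjusted p = 0.019; adjusted p = 0.78 with an estimated correlation). Tmem176a was at 3.86 ± 1.67 CPM in the controls and 10.9 ± 5.33 CPM in the libraries labelled Ythdf2 cKO. Tmem176b had a log2 fold change of 0.79 with a standard error of 0.44 (0.48 without control replicate 1 and 1.35 without control replicate 3). The median was 0.43 within each cage. The call ended without control replicate 3 (0.25) or Ythdf2 cKO replicate 1 (0.042), without the low-count filter (0.18) and with sample quality weights (0.085). The median was 0.66 without control replicate 1 and 0.42 without control replicate 2. It was 0.40 with total counts, 0.39 with the GC content and length correction, 0.42 with cage as a term and 0.17 with the melanoma covariate. Of single members 1 had an unadjusted p under 0.05, and 0 passed when adjusted over all genes or adjusted over the list alone.

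Markers of 3 other cell types were called as lists. Macrophage and monocyte markers had a median log2 fold change of -1.17 over 19 genes (camera adjusted p = 0.026; adjusted p = 0.96 with an estimated correlation). Scaled to total gene counts without the TMM factors, the sum of the markers was 878 ± 70.8 CPM in the controls. It was 919 ± 129 CPM in the libraries labelled Ythdf2 cKO (exact permutation p = 0.6, adjusted p = 1). The median of the list was -0.70 with total counts as the only scaling. The TMM factor of control replicate 3 was 0.713, and sums with the TMM factors were not tested. With total counts, however, the median was below 0 while the sum was not lower, so scaling alone does not account for the gap. Abundant members weigh most in a sum. Ccr2, chosen after its values were seen, held much of the sum, at 437 ± 60.0 and 469 ± 174 CPM with the TMM factors. Arg1 was at 23.4 CPM in control replicate 3 and from 0 to 3.89 CPM in the other libraries. Without control replicate 3 the median was 0.58, and the call also ended without Ythdf2 cKO replicate 1 (-0.61) or Ythdf2 cKO replicate 2 (-0.69), while it was -3.09 without Ythdf2 cKO replicate 3. It ended too with limma-voom (-0.68), without the low-count filter (-1.16), at a mean CPM of at least 5 (-0.24) and with sample quality weights (-0.14). Within cages 1 and 2 it was -1.95 and -2.64. Of the 19 genes 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone.

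Erythroid and platelet genes had a median of 2.39 over 9 genes (camera adjusted p = 2.61e-05; adjusted p = 0.78 with an estimated correlation). Hba-a1 was read 18 times in the controls and 276 times in the libraries labelled Ythdf2 cKO, 251 of them in replicate 2. Without that library the median was 1.24, without control replicate 3 it was 3.91, without mitochondrial, ribosomal RNA and haemoglobin genes it was 1.52, and within cages 1 and 2 it was 2.38 and 0.82. B and plasma cell genes had a median of 0.42 over 10 genes (adjusted p = 0.0047; adjusted p = 0.78 with an estimated correlation), and Jchain, the joining chain of secreted antibodies, was read 25 and 99 times. The sum of the B cell markers, scaled to total gene counts without the TMM factors, was 156 ± 68.0 and 157 ± 15.9 CPM (exact permutation p = 1), most of it from Ighm. The median was 2.31 without control replicate 3 and 0.78 without Ythdf2 cKO replicate 3, and the call ended with cage as a term (0.84) and with DESeq2 (0.40). It was 1.46 with limma-voom, 1.47 with quality weights, 0.96 without the low-count filter and 0.84 with total counts, and within cages 1 and 2 it was 1.78 and -0.24. Of single members, 2 erythroid and 0 B cell genes had an unadjusted p under 0.05, and 0 passed when adjusted over all genes or adjusted over the list alone.

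The title of the series names NF-kB, the inflammatory transcription factor, and Treg survival and function. NF-kB target genes had a median log2 fold change of -0.016, with 23 of 52 members above 0 and 29 below (camera adjusted p = 0.95), and the sign turned with total counts (0.077) or upper quartile factors (1.72e-04) as the scaling. Inhibitors of the NF-kB pathway had a median of 0.12, with 27 of 42 above 0 (adjusted p = 0.13), and passed as higher with DESeq2 (0.13). The Treg signature had a median of -0.029, with 14 of 33 above 0 (adjusted p = 0.92), while camera placed it in the higher direction and total counts gave 0.083. Of the members of these 3 lists 0 had an unadjusted p under 0.05, and 0 passed when adjusted over all genes or adjusted over the list alone. Among the targets, Gch1 was at 30.1 ± 1.56 CPM in the controls and 41.2 ± 10.3 CPM in the libraries labelled Ythdf2 cKO, and Csf2, a myeloid growth factor, at 4.28 ± 1.15 and 1.40 ± 1.12 CPM. Among the inhibitors, N4bp1 was at 153 ± 15.4 and 203 ± 47.5 CPM and Itch, a ubiquitin ligase, at 101 ± 13.8 and 126 ± 24.5 CPM. Among Treg genes, Izumo1r was at 64.4 ± 35.4 and 44.4 ± 10.2 CPM, and Cd83, held by both the target and the Treg list, at 109 ± 62.8 and 68.1 ± 7.47 CPM. Single libraries moved these differences in both directions. Without control replicate 1 the log2 fold change went from -0.54 to -0.13 for Izumo1r and from -0.68 to -0.35 for Cd83. Without control replicate 3 it was -0.88 for Izumo1r and -1.06 for Cd83. Without Ythdf2 cKO replicate 1 Gch1 went from 0.45 to 0.23, N4bp1 from 0.41 to 0.19 and Itch from 0.32 to 0.14. Their highest values with a library left out were 0.59, 0.50 and 0.43. Csf2 went from -1.61 to -1.06 without Ythdf2 cKO replicate 3 and to -2.10 without Ythdf2 cKO replicate 2.

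Within cages, these 3 lists lay above 0. The median difference was 0.14 in cage 1 and 0.15 in cage 2 for the targets, 0.31 and 0.24 for the inhibitors, and 0.13 and 0.30 for the Treg signature, each from 2 libraries against 1. The melanoma markers and mitochondrial ribosomal RNA lay lower in the libraries labelled Ythdf2 cKO within both cages. With cage as a term all 3 passed in the higher direction, with medians of 0.16, 0.25 and 0.19, and all 3 calls were lost when the correlation was estimated as well (adjusted p = 0.51 with an estimated correlation and cage as a term). Calls in the lower direction were made with sample quality weights for the targets (-0.17) and the Treg signature (-0.25), and for all 3 without both ends of the first principal component (-0.26, -0.17 and -0.42), where group and cage cannot be told apart. With the melanoma markers as a covariate none of the 3 passed (-0.044, 0.095 and -0.055). The targets passed as lower without Ythdf2 cKO replicate 1 (-0.22), were at -0.082 without control replicate 3, and lay above 0 without control replicate 1 (0.086), control replicate 2 (0.014), Ythdf2 cKO replicate 2 (0.022) or Ythdf2 cKO replicate 3 (0.039). The Treg signature passed as lower without control replicate 3 (-0.20), was at -0.20 without Ythdf2 cKO replicate 1, and lay above 0 without control replicate 1 (0.10), control replicate 2 (0.047), Ythdf2 cKO replicate 2 (0.029) or Ythdf2 cKO replicate 3 (0.043). The inhibitors passed as higher without control replicate 2 (0.19) or Ythdf2 cKO replicate 3 (0.18), and lay below 0 without control replicate 3 (-0.025) or Ythdf2 cKO replicate 1 (-0.063).

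**Figure D3:**
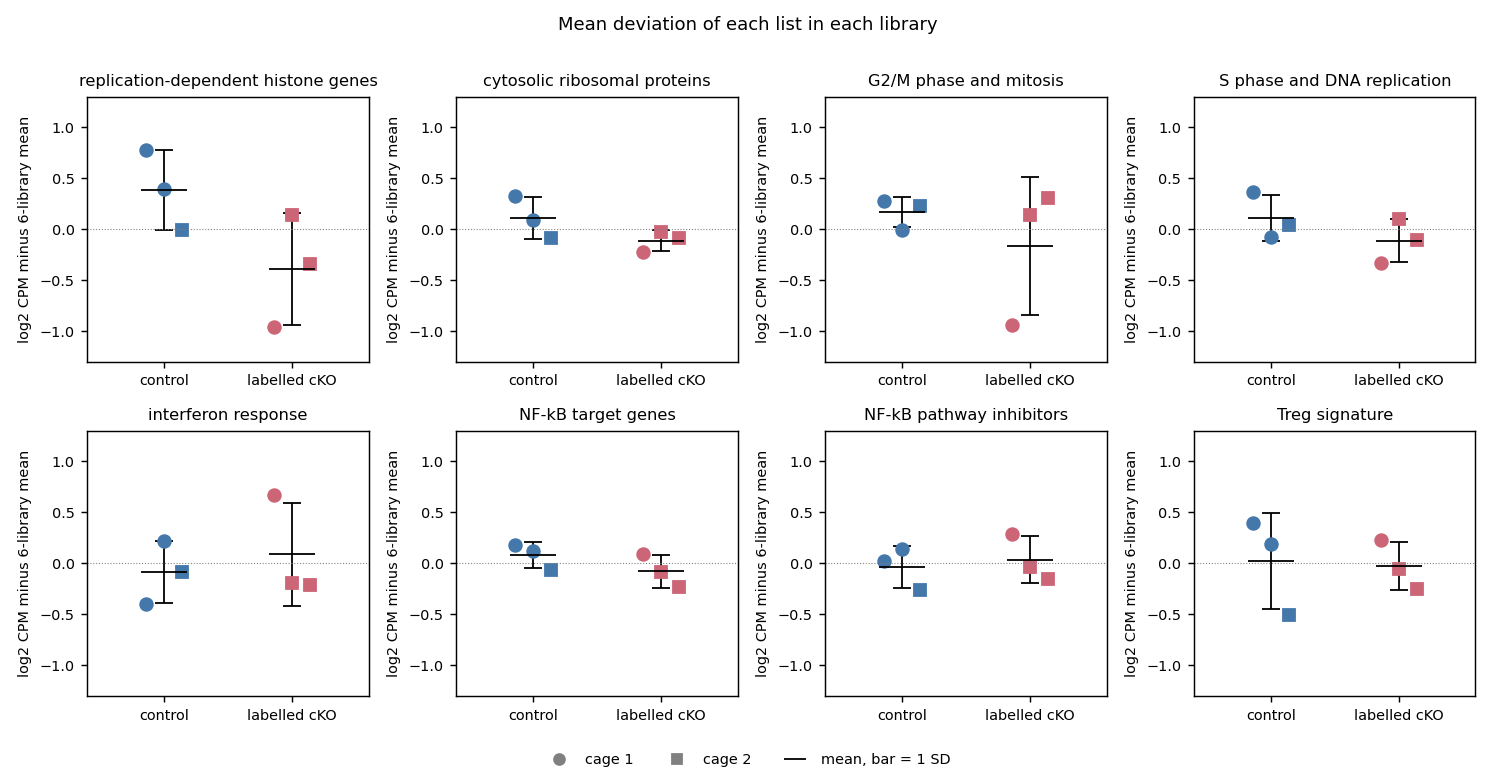
Mean deviation of 8 gene lists in each library, as log2 CPM minus the mean of the 6 libraries. Circles are cage 1, squares cage 2, and black marks the mean with a bar of 1 SD over 3 libraries; the histone genes run from -0.96 in Ythdf2 cKO replicate 1 to 0.78 in control replicate 1.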

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

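The tests of S phase, of cage, with the melanoma covariate and with the GC content and length correction were chosen after the pattern they bear on had been seen, as were the interaction with cage and the spread allowed around the 5% bound.

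Reads in no gene, a row outside the gene tests, were a larger share of all records in every library labelled Ythdf2 cKO than in any control. The mean was 31.7% against 26.4% in the controls (exact permutation p = 0.1, the smallest that 3 against 3 can give, adjusted p = 0.83). The share is not independent of the gene counts, since all records include them. Mitochondrial ribosomal RNA took 42.6% of the gene counts in control replicate 3, which had the lowest share, 24.6%. In the other libraries it took from 9.97% to 19.2% of the gene counts. Whether the groups stay apart with these reads left out of all records was not tested.

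The fitted difference between the groups differed between the cages for 6 genes, by an edgeR interaction term that rests on single libraries: cage 1 holds 1 library labelled Ythdf2 cKO and cage 2 holds 1 control, each assumed to vary like the rest, so the term cannot separate a cage from a library that stands apart. The interaction was 9.60 for Tyr, 4.40 for Met, 2.80 for Eps8, 5.52 for Syt4, -5.17 for Gm10800 and -3.35 for Gm24270 (log2, adjusted p from 0.0096 to 0.046; these genes were chosen after their values were seen). Tyr, the key melanin enzyme, was at 0 CPM in Ythdf2 cKO replicate 1, so its fitted value depends on the prior count. It was at 221 CPM in control replicate 3. Met, Eps8 and Syt4 were likewise lowest in Ythdf2 cKO replicate 1 and highest in control replicate 3. Gm10800 and Gm24270 stood out in control replicate 3, at 603 and 299 CPM. Outside the 12 lists described, the melanoma markers had a median difference of -2.95 within cage 1 and -0.78 within cage 2. Mitochondrially encoded mRNAs had -0.50 and -1.54. Of the 12 lists described, 5 also differed between cages (camera): interferon response by -0.52, G2/M and mitosis by 1.17, histone genes by 1.03, cytosolic ribosomal proteins by 0.48 and erythroid genes by -1.09. None of these holds with an estimated correlation (adjusted p = 0.98 with an estimated correlation).

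Fewer genes had an unadjusted p under 0.05 than chance gives on average, 213 against 659 expected. The other splits of the 6 libraries gave from 114 to 2623, so 213 lies within their range and may need no cause. Ythdf2 cKO replicate 1 standing apart does not account for the low count: without it 310 genes had such a p, against 704 expected. With cage as a term 1345 did, more than chance gives, so a difference between the cages may widen the spread within each group. With the melanoma markers as a covariate 645 did, below the recorded bound of 659, and by that bound alone tumour-cell RNA would not account for the low count. The gap is less than the sampling spread allowed afterwards, but that spread takes genes as independent. The test therefore cannot tell tumour-cell RNA apart from other cage differences. The sort on CD45, CD4 and Foxp3-GFP would remove intact melanoma cells, none of the 15 markers is in another list, and Dct and Tyrp1 reached 2013 and 1333 CPM in control replicate 3.

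The real split of the samples called 0 genes, a count that all 10 splits reach by construction and that says nothing about chance, and the highest other split gave 849. That split is the one between the cages, which points to a structure of the samples, and with cage as a term 0 genes passed (edgeR, 1345 at an unadjusted p under 0.05). For lists, 8 of the 10 splits gave as many as the real 9, and the highest other, again the cages, gave 29. With 10 splits no share under 0.05 can be reached.

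The lower histone genes held in 20 of 23 alternatives, as did the ribosomal protein genes. GC content and gene length do not account for it as a whole, since the median was -0.54 after the correction against -0.68 before, and 0 of 10000 random lists matched on expression, GC content and length had a median as low. Other single-exon protein-coding genes had a median of 0.004 over 156 genes, which argues against a general loss of intronless transcripts. These genes were not chosen by length, so they do not test a loss of compact intronless transcripts alone. Fewer cells in S phase stay open: the replication genes lay lower too, at -0.18, and no value here says how far they would move with histone mRNAs. Deletion of Ythdf2 may be a cause, as a hypothesis only. The call is lost with an estimated correlation, and Ythdf2 itself did not pass the threshold. The preset correlation also called the list in other splits. Control replicates 1 and 2 with Ythdf2 cKO replicate 2 gave -0.66 (camera adjusted p = 1.65e-13), and with Ythdf2 cKO replicate 3 -0.39 (2.48e-06). Control replicates 1 and 3 with Ythdf2 cKO replicate 2 gave -0.47 (3.40e-06), and the cages -0.32 (0.046). Control replicate 1 with Ythdf2 cKO replicates 1 and 3 gave 0.17, the other direction (0.029). The rest had an adjusted p from 0.055 to 0.76.

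Ythdf2 transcripts at the control level could come from tumour cells in the sorted libraries. With the melanoma markers as a covariate the 95% interval of its log2 fold change ran from -0.44 to 0.25, wholly above -1. Without the covariate the interval already lay above -1, from -0.47 to 0.28. A covariate also does not remove tumour reads, so the test cannot decide this. Ythdf2 cKO replicate 1 had the lowest melanoma markers, at 1.14 log2 CPM, and held Ythdf2 at 90.1 CPM. Transcripts that lose an exon and are still counted, and a label or deletion that did not take effect, stay open, since no exon-level counts were analysed here.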

How the results depend on the processing

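The melanoma covariate, quality weights, the GC content and exon length correction, the fit without the ends of the first principal component and cage with an estimated correlation were chosen after seeing the data. Gene counts stayed at 0 in both directions under all alternatives except a pair. Without a low-count filter 26 genes were higher and 7 lower; 14 of these 33 are also tested with the filter, and 20 have over 90% of their reads in 1 library. Without both ends of the first principal component, which leaves cage 1 controls against cage 2 libraries, 427 were higher and 33 lower. Of the 427, 410 are also higher in cage 2, where 33.4 are expected of independent lists. The cage comparison holds the same libraries, so the lists are not independent and much of the overlap is built in. Group and cage cannot be told apart in that setting. Total counts as the only scaling moved the median of all genes to 0.14.

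Lists called higher and lower numbered 4 and 5. They were 7 and 9 with DESeq2, 8 and 3 without the filter, 2 higher at a mean CPM of at least 5, 12 and 10 with cage as a term, 7 and 14 without the ends of the first component, 11 lower with quality weights, and 0 and 0 with fry or an estimated correlation, with or without cage. Leaving out each library gave 3 to 7 higher and 5 to 10 lower, and 0 to 0 genes in each direction. Histone genes and ribosomal proteins were lower past the threshold in 20 of 23 alternatives, all but fry and the estimated correlation with or without cage; histone medians ran from -0.90 to -0.50.

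Ythdf2 lay between -0.16 and 0.023 without each library, and at 0.021 with total counts. NF-kB targets ran from -0.22 to 0.086 without each library, 1.72e-04 with upper quartile factors, 0.077 with total counts, 0.0077 at the stricter filter, 0.16 with cage, 0.072 with the GC and length correction, -0.17 with quality weights and -0.26 without the ends, both past the threshold as lower. The inhibitors ran from -0.063 to 0.19 without each library, 0.13 with DESeq2, 0.22 with total counts and 0.25 with cage. They were at -0.068 with quality weights and -0.17 without the ends, the last past as lower. The Treg signature ran from -0.20 to 0.10 without each library, 0.083 with total counts, 0.19 with cage, 0.070 with the GC and length correction, -0.25 with quality weights and -0.42 without the ends, both past as lower. The cause of these shifts was not tested.

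Of 1121 values of the other 57 named genes, 18 changed sign and 6 passed, all without the ends: Il17rb, Hist1h1e, Il5, Cd83, Izumo1r and Alas2. With cage, Il1r1 was -0.031. With the melanoma covariate, the Cd4 log2 fold change was -0.0168. With quality weights, Foxp3 was -0.22, Cd4 -0.16, Mx1 -0.12 and interferon response -0.041. Without the ends, Foxp3 was -0.39, Cd4 -0.35, Mx1 -0.36, Adgre1 0.68, T helper 17 genes -0.044, interferon response -0.11, G2/M genes 0.0036 and macrophage markers 1.02. Without each library, Foxp3 ran from -0.24 to 0.18, Cd4 from -0.19 to 0.21, Il1r1 from -0.026 to 1.19, Mx1 from -0.48 to 2.00, Adgre1 from -3.55 to 0.16, Ighm from -0.65 to 0.040, T helper 17 genes from 0.042 to 0.66, interferon response from -0.11 to 0.40, G2/M genes from -0.44 to 0.029 and macrophage markers from -3.09 to 0.58. The cause was not tested.

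Whether replicate numbers pair the libraries cannot be told from cage. The correlations of same-numbered deviations were 0.41 and 0.55 for numbers 1 and 3, each within a cage, and -0.24 for number 2, across cages. Differently numbered libraries of the same cage and different groups gave 0.46 and 0.27. With the replicate block 0 genes passed in either direction, with 5 lists higher and 4 lower, while S phase genes no longer passed and the B cell median was 1.07. Depth limits rare transcripts most, above all in Ythdf2 cKO replicate 1.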

Other observations

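The comparison between cages was chosen after the data were seen. The test with 3 prime UTR length was chosen after the motif result was seen, with its bound written before its own value was.

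The cages differed more than the groups. With the group held fixed, 1031 genes were higher and 485 lower in cage 2 than in cage 1 (edgeR, adjusted p under 0.05, 3 libraries a cage). The higher genes with the smallest p include pigment-cell genes: Mitf, the melanocyte regulator, had a log2 fold change of 4.22, Mlph 4.33, Slc45a2 3.92 and Trpm1 3.48; they were chosen after their values were seen. Melanoma markers had a median of 4.26, fibroblast markers 5.14 and macrophage markers 3.10, while T cell receptor signalling genes had -0.59, Treg effector genes -0.63 and the Treg signature -0.64 (camera adjusted p from 4.91e-10 to 1.57e-04, preset correlation; adjusted p from 0.34 to 0.42 with an estimated correlation). The sum of the macrophage markers was 916 CPM in cage 1 and 881 CPM in cage 2, scaled to total gene counts without the TMM factors. The medians use the TMM factors, but the mean factors of 1.09 in cage 1 and 0.934 in cage 2 differ too little to give 3.10. Abundant members such as Ccr2 weigh most in the sums, so these sums do not test the macrophage median.

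A hypothesis was that mRNAs with more m6A consensus motifs (DRACH) in the 3 prime UTR are higher without Ythdf2, as slower decay would give. Across 11197 protein-coding genes, 98.2% of those tested, the partial Spearman rho of motif number and log2 fold change was 0.088, past the bound of 0.05 set beforehand, with coding length and mean expression held fixed; genes are not independent replicates. The highest of the other splits gave 0.082, and 10 splits are too few for a share under 0.05. With 3 prime UTR length held fixed too, rho was 0.017 (up to 0.021 in size in the other splits), and within cages 1 and 2 it was 0.041 and 0.0035 without that length. The length of 3 prime UTRs rather than their motifs may carry the relation, and the motif hypothesis stays open at best.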
